A study of Mus musculus with 6 samples.

How the data were processed

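The data are RNA sequencing profiles of small intestine from 3 mice labelled wild type (WT) and 3 labelled TLR4ΔIEC. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I, checked on a Bioanalyser and made into libraries by standard Illumina protocols. The submitters' processing notes name fastp, HISAT, RSEM and the mouse genome build GRCm38.p5, without versions or settings, and whether reads were assigned by strand is not given in the sources used here. The deposited table gives TPM per gene and library, per the file headers, with the authors' own group means beside them, which were not used. TPM are scaled so that each library sums to the same total, so that a gene that takes a large share, such as an alpha-defensin, lowers all others in the same library. Read totals cannot be recovered from TPM: depth is unknown, and no counting interval is given. Without strand, overlapping or antisense genes cannot be told apart.

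Among the listed genes, 312 have no name and 52147 have an identifier in GENCODE M21, whose GRCm38 coordinates are given. Library groups and replicate numbers come from the sample titles. The design text gives 3 mice per genotype. Pearson correlations of log2 values were 0.939 to 0.977 within a genotype and 0.920 to 0.948 between genotypes, so no library was a copy of another. Principal components were computed on the centred log2(TPM + 1) of the tested genes. Y-linked genes were present in each of the 6 libraries, such as Eif2s3y at 12.9 to 26.7 TPM. All 6 libraries were used.

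Genes with a mean of at least 1 TPM over the 6 libraries (13458) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, two-sided, with genotype as the single term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and are TLR4ΔIEC minus WT. Replicate numbers of the labels name no shared animal and were not used as a block. Genes were named by a rule set before the data were examined, as were the tests across genes and lists, the 44 gene lists and most alternatives, but not all tests of explanations: Tlr4 first, then the genes past the threshold with an official symbol whose 3 libraries of one genotype all lie above the 3 of the other (up to 12 per direction by fold change, and where fewer passed, the smallest p-values up to 6, said not to pass), then for each described list up to 4 members past the threshold, filled up to 2 with the members of highest mean TPM. Some genes that the rule picks are not given. Other genes were chosen after their values were seen. They are the 7 unnamed, predicted or immunoglobulin calls, members that passed over their list alone, and examples such as Lyz1, Mmp7, Sqle, Hmgcs1, Slc10a2, Slc51b, Fgf15, Ighm, Cd79a, Ifit1, Ifit3, Cldn2, Egr1 and Hox genes. The described lists are those past the threshold of camera.

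Lists with 3 or more tested members (43, a list of sex-linked genes being only a check) were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. GO and KEGG terms with 10 to 300 tested members were tested with camera and adjusted within each source. Counts adjusted over the list alone use the p-values of the list's members only. Single values were compared by exact permutation tests, for which 3 against 3 allows no p below 0.1. The fit was tested on simulated data with the means and spreads of the 13458 genes, each drawn independently of the others. Of 200 changed genes, 35 of 100 changed by 1 on the log2 scale and 70 of 100 changed by 2 were recovered, with 3 false calls. A shifted list of 20 genes gave a camera p of 2.06e-25, against 0.245 for an unshifted one. The simulated genes had no inter-gene correlation, whereas that estimated for the Paneth list was 0.71. The simulation therefore does not show how camera performs on the real lists.

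Alternatives were pseudocounts of 0.1 and 5 TPM, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, TPM rescaled without the 20 highest genes, eBayes without trend, robust eBayes, array weights, a replicate block, each library left out in turn, a fold change of at least 2 as well, and camera without the 20 highest genes. After seeing the data, TPM rescaled without alpha-defensin, mitochondrially encoded, Rn18s, Cmss1 and Gphn genes (the last 3 termed 18S-like) was added. Figures were drawn with matplotlib 3.10.9.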

Results

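RNA sequencing was done on total RNA from the small intestine of 6 mice aged 8 to 12 weeks, 3 labelled wild type (WT) and 3 labelled TLR4ΔIEC. The series title names the question, the effect of depleting intestinal TLR4, the receptor for bacterial lipopolysaccharide. The labels do not give the stretch of small intestine that was taken, and the 6 samples carry the same collection date. The deposited table gives each gene in TPM, a transcript abundance scaled to the same total in each library. Genes above 0 TPM numbered from 20031 in TLR4ΔIEC replicate 2 to 21842 in TLR4ΔIEC replicate 3. TLR4ΔIEC replicate 2 stood apart in other ways: it had 12221 genes at 1 TPM or more, against 13197 to 13634 in the other libraries, and Rn18s, an 18S ribosomal RNA gene, at 12836 TPM, against 3806 to 7032 TPM. On the first principal component, with 41.4% of the variance, it lay at 62.4, TLR4ΔIEC replicates 1 and 3 at 5.62 and 21.4, and the WT libraries at −34.4 to −22.4. TPM keep no read totals, so the depth of each library is unknown.

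Tlr4 (ENSMUSG00000039005, chromosome 4, 66827584 to 66930284, plus strand, GRCm38) was examined first because it is the targeted gene. It stood at 0.65, 0.57 and 0.70 TPM in the WT libraries and at 1.29, 1.22 and 4.81 TPM in the libraries labelled TLR4ΔIEC, so each of the latter lay above each WT library. The means were 0.640 ± 0.0656 and 2.44 ± 2.05 TPM (SD, n = 3 each), and the log2 fold change was 0.92 (SE 0.40, limma adjusted p = 0.243). An exact two-sided permutation test of the TPM gave p = 0.1, the smallest that 3 against 3 allows. Over the alternatives that gave a value the log2 fold change ran from 0.37 to 1.495 and the adjusted p from 0.0839 to 0.480, and without TLR4ΔIEC replicate 3 the gene fell below the filter and had no value. The difference did not pass the threshold, and its direction was not that of a loss of Tlr4. By the plan set beforehand a fall was not required, since the deletion is in epithelial cells of a whole tissue and may leave exons. No exon-level values are in the table. The lists of immune and stromal cell genes below had transcripts in all 6 libraries, so the tissue was not epithelium alone. The level of Tlr4 thus cannot show whether the labels are right or exchanged. Every direction below therefore compares libraries labelled TLR4ΔIEC with libraries labelled WT.

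Across the genome, 6 genes with an official symbol fell past the threshold in the libraries labelled TLR4ΔIEC. Lct (ENSMUSG00000026354, chromosome 1, 128284756 to 128328318, minus strand), which encodes lactase, fell from 49.6 ± 24.7 to 0.520 ± 0.350 TPM (log2 fold change −4.93, SE 0.43, adjusted p = 0.0316). Dnase1 (ENSMUSG00000005980, chromosome 16, 4036942 to 4040024, plus strand), a secreted nuclease, fell from 47.0 ± 9.31 to 3.04 ± 1.54 TPM (log2 fold change −3.62, SE 0.28, adjusted p = 0.0245). Gata4 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692, minus strand), a transcription factor of the proximal small intestine, fell from 21.9 ± 8.23 to 1.24 ± 0.986 TPM (log2 fold change −3.41, SE 0.39, adjusted p = 0.0494). Enpp7 (ENSMUSG00000046697, chromosome 11, 118988188 to 118993221, plus strand), the intestinal alkaline sphingomyelinase, fell from 450.2 ± 105.1 to 53.8 ± 22.4 TPM, with a log2 fold change of −3.09. Ugt2a3 (ENSMUSG00000035780, chromosome 5, 87324972 to 87337195, minus strand), a glucuronosyltransferase, fell from 13.6 ± 4.07 to 0.860 ± 0.470 TPM, with a log2 fold change of −2.97. Apoa4 (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459, plus strand), an apolipoprotein of chylomicrons, fell from 628.5 ± 241.5 to 102.5 ± 13.4 TPM, with a log2 fold change of −2.55. Each of these 6 genes lost its call when WT replicate 2 was left out (adjusted p 0.0789 to 0.181) and when TLR4ΔIEC replicate 2 was left out (0.0640 to 0.104). WT replicate 3 also decided Dnase1, Gata4, Enpp7, Ugt2a3 and Apoa4 (0.0862 to 0.202 without it), TLR4ΔIEC replicate 3 decided Lct, Gata4, Ugt2a3 and Apoa4 (0.0511 to 0.0880), and WT replicate 1 decided Gata4 and Apoa4 (0.0615 and 0.0518). Over all alternatives the adjusted p of these genes ran from 0.00329 for Lct to 0.202 for Gata4 and Enpp7.

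In the other direction 3 such genes rose past the threshold. S100g (ENSMUSG00000040808, chromosome X, 162961992 to 162964599, minus strand), the calcium-binding protein calbindin-D9k, rose from 14.0 ± 6.60 to 112.4 ± 13.1 TPM (log2 fold change 3.00, SE 0.29, adjusted p = 0.0350). Grm4 (ENSMUSG00000063239, chromosome 17, 27422387 to 27521403, minus strand), a metabotropic glutamate receptor, rose from 0.257 ± 0.0306 to 4.18 ± 0.587 TPM, with a log2 fold change of 2.04. Edn2 (ENSMUSG00000028635, chromosome 4, 120161206 to 120167360, plus strand), an endothelin, rose from 12.8 ± 1.06 to 30.2 ± 1.17 TPM, with a log2 fold change of 1.18 and an adjusted p of 0.0412. Of the next genes by p-value, these did not pass: Trpm6, a magnesium channel, had a log2 fold change of 1.87 (adjusted p = 0.0689), and Slc25a48 of 2.45 (adjusted p = 0.0689). S100g, Grm4 and Edn2 lost their calls without WT replicate 2 (adjusted p 0.0928, 0.172 and 0.208), WT replicate 3 (0.195, 0.202 and 0.202), TLR4ΔIEC replicate 2 (0.0721, 0.0640 and 0.0876) and TLR4ΔIEC replicate 3 (0.0737, 0.0836 and 0.0912), and Grm4 and Edn2 without WT replicate 1 (0.0549 and 0.0592). Over all alternatives the adjusted p ran from 0.00469 to 0.195 for S100g, from 0.0202 to 0.202 for Grm4 and from 0.0267 to 0.208 for Edn2, which also lost its call under each other scaling.

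**Figure D1:**
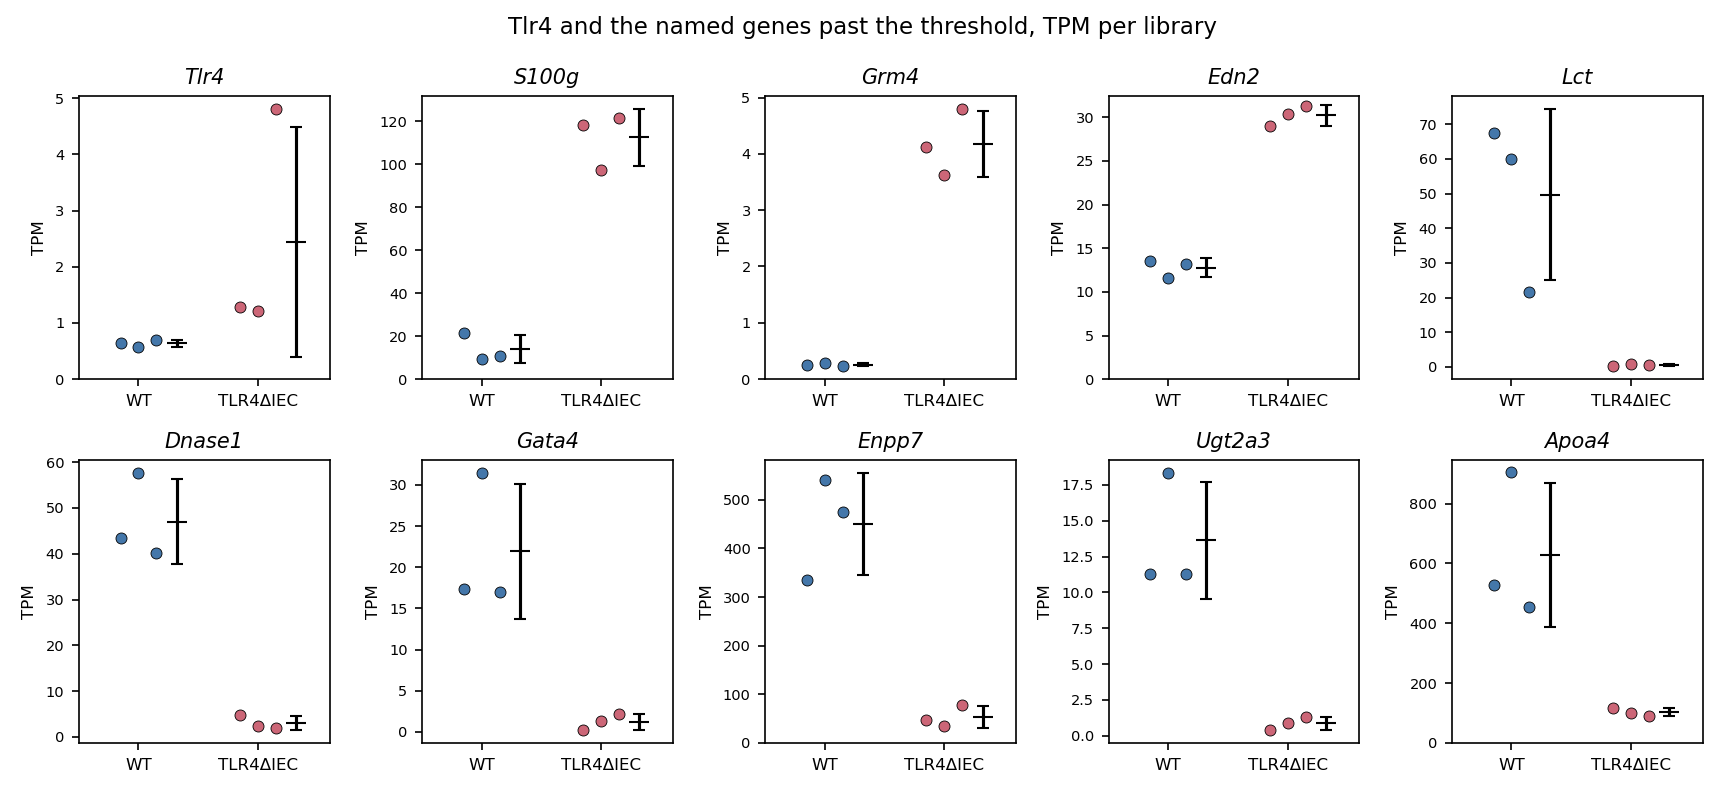
TPM (y axis, linear) of Tlr4 and of the 9 named genes past the threshold in each library, by genotype label (x axis); points are libraries, and the bar beside them is the mean with the SD of 3 libraries. Tlr4 lies between 0.57 and 0.70 TPM in WT and between 1.22 and 4.81 TPM in the libraries labelled TLR4ΔIEC, and Lct lies below 1 TPM in each of the latter.

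In all, 16 of 13458 tested genes passed an adjusted p of 0.05, 6 higher and 10 lower, each by at least 2-fold. The other 7 were the immunoglobulin segments Ighv1-63, Ighv14-1 and Ighv14-4, which were lower, the predicted genes Gm11027 and Gm2061, which were higher, and the unnamed MSTRG.5964, lower, and MSTRG.12184, higher. These 7 were chosen after their values were seen, and Gm11027 is listed at 0 in each WT library and MSTRG.5964 at 0 in each library labelled TLR4ΔIEC. The 3 TPM of one genotype lay apart from the 3 of the other in 3712 genes (27.6%), where chance gives 10%, and 2847 genes had an unadjusted p under 0.05, a number that fell to between 1643 and 1870 under the other scalings. The median log2 fold change of all tested genes was 0.16. Median-of-ratios scaling moved that median to −0.01 and gave 3 higher and 13 lower genes, and quantile normalization gave 4 and 14. With the 20 highest genes left out the split was 3 and 8, and with alpha-defensin, mitochondrial and 18S-like genes left out it was 3 and 11, at a median of −0.13. Leaving out TLR4ΔIEC replicate 1 raised the number of calls to 367, and leaving out WT replicate 1 raised it to 32, while it fell to 3 without WT replicate 3, to 5 without TLR4ΔIEC replicate 3 and to 0 without WT replicate 2 or TLR4ΔIEC replicate 2, where limma gave 1681 and 2651 genes with an unadjusted p under 0.05. With no filter 0 of 26866 genes passed, where limma gave 3377 with an unadjusted p under 0.05, with a mean of at least 5 TPM 7 passed, and with array weights 136, 98 higher and 38 lower. With the replicate number as a block 1 passed, and it was not among the 16.

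Gene lists fixed before the data were examined were then tested with camera, which sets a list against all other genes. Of 43 lists, 26 passed, 10 higher and 16 lower. None passed in camera with an estimated inter-gene correlation, where the smallest adjusted p was 0.567. By fry, which asks whether a list's genes move one way on balance, 6 passed: tight junction, cholesterol, glycolysis, cell death, autophagy and colon, which did not pass in camera (adjusted p 0.0379 to 0.0391). These 6 lists were all higher. Since fry sets a list against no change, it makes no allowance for the median of 0.16 of all genes, and it was not run under the other scalings. The other called lists did not pass by fry, with an adjusted p of 0.153 for Paneth, 0.165 for proximal small intestine, and 0.0522 for the ileal, immediate early and TLR4 signalling lists. The Paneth, proximal small intestine, stem cell, cell cycle, T and NK cell, endothelium, cholesterol, tight junction and immediate early lists kept their call whichever single library was left out, and the libraries that decide the other calls are named with the lists. Members that are named because they passed over their own list were chosen after their values were seen, and a list's median is to be set against the 0.16 of all genes.

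Markers of the proximal small intestine were lower and markers of the ileum higher in the libraries labelled TLR4ΔIEC. Of 11 proximal genes, Lct and Gata4 fell and S100g rose over all genes tested, and 6 were lower and 2 higher adjusted over the list alone. Fabp1, the liver-type fatty acid binding protein, averaged 424.5 ± 345.6 TPM in WT and 32.8 ± 34.6 TPM in the libraries labelled TLR4ΔIEC, and the cytochrome Cyp2b10 23.9 ± 9.82 and 1.77 ± 1.27 TPM. Slc40a1, the iron exporter ferroportin, went the other way, like S100g, with a log2 fold change of 1.51. The list's median log2 fold change was −0.67 (camera adjusted p = 2.92e-05, and adjusted p = 0.567 with an estimated correlation). Of 12 genes of the ileum and bile acid uptake, none passed over all genes, and 8 were higher and 1 lower adjusted over the list alone. The ileal bile acid binding protein Fabp6 averaged 4961 ± 2494 TPM in WT and 22955 ± 12644 TPM in the libraries labelled TLR4ΔIEC (log2 fold change 2.17, SE 0.60, adjusted p = 0.124). The bile acid transporters Slc10a2 and Slc51b had log2 fold changes of 1.53 and 1.02. The exception was Ang4, an antimicrobial angiogenin of Paneth cells that sits on both lists, with a log2 fold change of −2.97. Fgf15, the ileal hormone, was picked out after its values were seen because it did not follow: it read 0.70, 33.2 and 27.6 TPM in WT and 1.40, 28.5 and 20.3 TPM in the libraries labelled TLR4ΔIEC (log2 fold change −0.04), and it turned to 0.72, 0.59 and 1.08 without WT replicate 2, WT replicate 3 and TLR4ΔIEC replicate 1. The ileal median was 1.02 (camera adjusted p = 0.00673, and adjusted p = 0.583 with an estimated correlation), and the call was lost without TLR4ΔIEC replicate 2 (adjusted p = 0.0739, range over alternatives 5.79e-06 to 0.0739).

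Of 25 absorptive enterocyte genes, Lct and Apoa4 fell over all genes, and 7 were lower and 5 higher adjusted over the list alone. Under the other scalings 9 to 12 were lower and 1 to 3 higher, with 9 and 1 under median-of-ratios scaling. The 5 higher ones were the brush border enzymes Treh, Anpep, Mep1a and Mep1b and the sterol transporter Npc1l1, with log2 fold changes of 0.86, 0.87, 1.34, 0.52 and 0.49. The list as a whole was lower (median −0.16, camera adjusted p = 0.00162, and adjusted p = 0.583 with an estimated correlation), but not without TLR4ΔIEC replicate 1 (adjusted p = 0.0968, range over alternatives 3.95e-06 to 0.0968). Of 6 colon genes, the mucin Muc3 and the acute phase protein Saa1 were higher adjusted over the list alone, with log2 fold changes of 1.28 and 2.51, and the list did not pass (median 0.44, camera adjusted p = 0.140), although it did with alpha-defensin, mitochondrial and 18S-like genes left out.

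Paneth cell genes were lower. Of 29 tested, 28 had negative fold changes, and 26 were lower adjusted over the list alone, but none over all genes. Defa24 averaged 35735 ± 4912 TPM in WT and 12090 ± 10273 TPM in the libraries labelled TLR4ΔIEC (log2 fold change −1.90, SE 0.60, adjusted p = 0.152), and Defa20 had a log2 fold change of −1.72. Lysozyme Lyz1 stood at 9133, 7142 and 7956 TPM in WT and at 6637, 1314 and 1968 TPM in the libraries labelled TLR4ΔIEC, and the matrix metalloproteinase Mmp7 had a log2 fold change of −1.50. The list's median was −1.59 (camera adjusted p = 4.83e-26, and adjusted p = 0.567 with an estimated correlation). Adjusted over the list alone, 27 of 29 were lower under median-of-ratios scaling and 26 of 29 under quantile normalization. With the 20 highest genes left out 20 of 22 were lower, and 8 of 9 where the alpha-defensins were left out. TLR4ΔIEC replicate 1 lay between WT and the other two: its mean log2 level over the list was 0.22 above the mean of the 6 libraries, against −1.69 and −0.87 in replicates 2 and 3 and 0.70 to 0.90 in WT. The 45 alpha-defensin genes in the table, which share near-identical sequence and are therefore uncertain one by one, took 26.8 ± 1.76% of the TPM in WT and 10.1 ± 7.26% in the libraries labelled TLR4ΔIEC (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible).

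**Figure D2:**
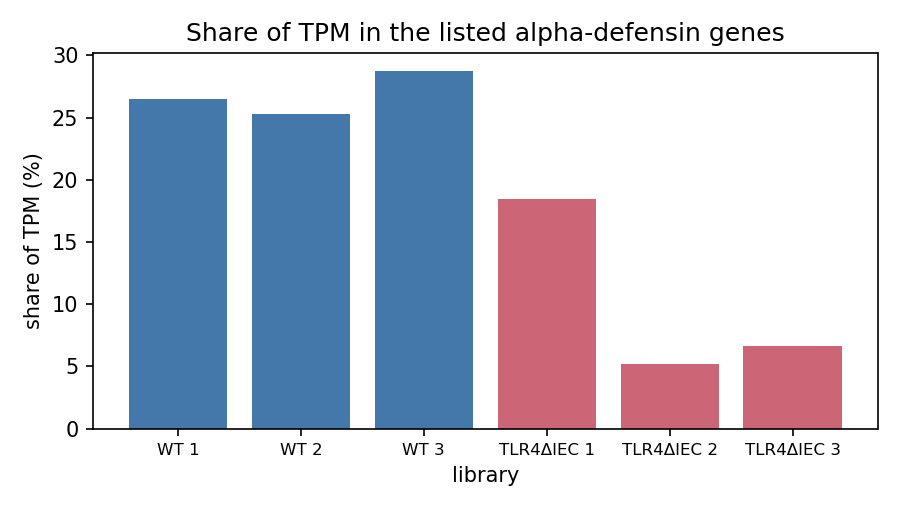
Share of each library's TPM (y axis, percent, from 0) taken by the 45 listed alpha-defensin genes, one bar per library (x axis). WT libraries hold 26.5, 25.3 and 28.7%, and the libraries labelled TLR4ΔIEC hold 18.4, 5.21 and 6.61%.

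Goblet cell genes went partly the other way. Of 16, Muc2, Fcgbp, Clca1 and Tpsg1 were higher adjusted over the list alone and none over all genes. Muc2, the gel-forming mucin, averaged 104.4 ± 22.2 TPM in WT and 329.6 ± 89.8 TPM in the libraries labelled TLR4ΔIEC, and Fcgbp 716.2 ± 25.3 and 2028 ± 619 TPM. As a list they did not pass (median 0.25, camera adjusted p = 0.135). With alpha-defensin, mitochondrial and 18S-like genes left out the median turned to −0.05 while the list passed as higher, and it also passed without TLR4ΔIEC replicate 3 (adjusted p = 0.00494, range over alternatives 0.00494 to 0.544). Stem cell genes were lower as a list of 14 (median −0.33, camera adjusted p = 0.00177, and adjusted p = 0.583 with an estimated correlation) with no member past either adjustment. The crypt marker Olfm4 had a log2 fold change of −1.53 and the Wnt target Axin2 of 0.61. The 23 cell cycle genes had a median of −0.23 (camera adjusted p = 1.56e-05, and adjusted p = 0.583 with an estimated correlation), with log2 fold changes of −0.30 for Ube2c and 0.05 for Pcna, which turned negative under each other scaling, without WT replicate 1 (−0.01) and without TLR4ΔIEC replicate 1 (−0.10). Among 13 enteroendocrine genes, the incretin Gip was lower adjusted over the list alone (−1.31), while Pyy and Sct had values of 1.21 and 0.97. That list passed (median −0.17, camera adjusted p = 0.0281), but not in camera with other settings: adjusted p = 0.592 with an estimated correlation, 0.484 without WT replicate 1 and 0.0625 without TLR4ΔIEC replicate 3 (range over alternatives 0.00208 to 0.484). It was also lost under median-of-ratios scaling, quantile normalization and with alpha-defensin, mitochondrial and 18S-like genes left out. The tuft cell list and the list of Notch and secretory lineage genes did not pass (medians 0.18 and 0.16, camera adjusted p = 0.522 and 0.985). Both medians turned negative with alpha-defensin, mitochondrial and 18S-like genes left out, and that of the Notch list also under median-of-ratios scaling and with the 20 highest genes left out. Both tests pointed lower than all genes, but higher under quantile normalization, and the tuft test also with alpha-defensin, mitochondrial and 18S-like genes left out. The tuft list passed as lower without TLR4ΔIEC replicate 3 (adjusted p = 0.00603, range over alternatives 0.00603 to 0.926).

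Of 19 B and plasma cell genes, the immunoglobulin constant genes Igha and Igkc, the plasma cell receptor Tnfrsf17 and the secretory pathway gene Derl3 were lower adjusted over the list alone. Igha averaged 4267 ± 511 TPM in WT and 1235 ± 639 TPM in the libraries labelled TLR4ΔIEC (log2 fold change −1.96, SE 0.45, adjusted p = 0.101), and Igkc had a log2 fold change of −1.80. The B cell genes Ighm and Cd79a did not follow, with log2 fold changes of 0.84 and 0.36. Ighm and Cd79a turned negative without TLR4ΔIEC replicate 3 (−0.06 and −0.49), and Cd79a also without TLR4ΔIEC replicate 1 (−0.12). The list's test was lower (camera adjusted p = 0.0102) while its median was 0.44 and its mean −0.03. The test was lost with an estimated correlation (adjusted p = 0.643) and under each other scaling. It was lost without WT replicate 3 (adjusted p = 0.0912) and turned to higher without TLR4ΔIEC replicate 2 (adjusted p = 0.864, range over alternatives 1.56e-05 to 0.864). T and NK cell genes were lower as a list of 21 (median −0.35, camera adjusted p = 4.99e-05, and adjusted p = 0.592 with an estimated correlation), with log2 fold changes of −0.84 for Gzma and −0.72 for Gzmb and no member past either adjustment. Of 14 macrophage and dendritic cell genes, the lysosomal protease Ctss was higher adjusted over the list alone (1.05, adjusted p = 0.0800 over all genes) and Lyz2 had a value of −0.38, which turned to 0.41 without TLR4ΔIEC replicate 2. The Ctss call over the list was lost under quantile normalization and with alpha-defensin, mitochondrial and 18S-like genes left out. The list was lower (median −0.24, camera adjusted p = 0.0216, and adjusted p = 0.643 with an estimated correlation), but not under any other scaling. It was lost without WT replicate 1, TLR4ΔIEC replicate 2 or TLR4ΔIEC replicate 3 (adjusted p 0.122, 0.658 and 0.0867, range over alternatives 6.06e-05 to 0.658). Of 3 neutrophil genes, Ltf was higher and Mmp9 lower adjusted over the list alone, and neither this list nor that of 3 mast cell genes passed (medians −1.51 and −1.13, camera adjusted p = 0.0976 and 0.0588). The neutrophil list passed without TLR4ΔIEC replicate 1 or 2 (adjusted p 0.0229 and 0.0278, range 0.0229 to 0.474), and the mast cell list without WT replicate 2 or 3 (0.0108 and 0.0190, range 0.0108 to 0.291).

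Genes of the TLR4 pathway other than Tlr4 were higher as a list of 21, of which 19 had positive fold changes and none passed either adjustment (median 0.38, camera adjusted p = 0.0226, and adjusted p = 0.583 with an estimated correlation). The signal inhibitor Tollip had a log2 fold change of 0.27 and Nfkb1 of 0.26, and both turned negative under quantile normalization and with alpha-defensin, mitochondrial and 18S-like genes left out. The list lost its call once alpha-defensin, mitochondrial and 18S-like genes were left out, and without WT replicate 3, TLR4ΔIEC replicate 2 or TLR4ΔIEC replicate 3 (adjusted p 0.0652, 0.0519 and 0.0503, range over alternatives 2.22e-04 to 0.0829). Of 6 other Toll-like receptors, Tlr3 was higher adjusted over the list alone (0.94), with 0 under each other scaling, and the list did not pass (median 0.05, camera adjusted p = 0.876). Its median turned negative under each other scaling but quantile normalization. Its test pointed lower than all genes, but higher under median-of-ratios scaling and quantile normalization. Targets of NF-kB and inflammatory cytokines did not pass either (13 genes, median 0.15 with a test that pointed lower than all genes, camera adjusted p = 0.299), and the test pointed higher with alpha-defensin, mitochondrial and 18S-like genes left out. None of these 13 passed either adjustment. Over the list alone 3 were lower under median-of-ratios scaling, and 3 lower and 1 higher under quantile normalization. Of 21 epithelial antimicrobial genes, Saa1 and the nitric oxide synthase Nos2 (1.05) were higher adjusted over the list alone, and the list did not pass (median 0.78, camera adjusted p = 0.254), although it did under median-of-ratios scaling, quantile normalization and with alpha-defensin, mitochondrial and 18S-like genes left out.

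Type I interferon response genes separated libraries within each genotype. All 26 tested genes had positive fold changes and none passed either adjustment. Isg15, a ubiquitin-like protein, read 202.1, 42.9 and 38.1 TPM in WT and 1555, 371.2 and 33.7 TPM in the libraries labelled TLR4ΔIEC. Irf7, the interferon regulator, had a log2 fold change of 2.45, Ifit1 of 1.78 and Ifit3 of 2.08. The list's median was 1.53 (camera adjusted p = 0.0216, and adjusted p = 0.702 with an estimated correlation). The call was lost without WT replicate 2 or 3 (adjusted p 0.105 and 0.0673) and without TLR4ΔIEC replicate 1 or 2 (0.726 and 0.338), with a range over alternatives of 8.19e-11 to 0.726. Genes of antigen presentation by MHC class I had positive fold changes in all 16 tested members, of which H2-T3 and Tapbp passed over the list alone, with log2 fold changes of 0.80 and 0.91. Under the other scalings 0 passed, except 2 with the 20 highest genes left out. B2m and H2-K1 had values of 0.78 and 0.87. The list passed (median 0.54, camera adjusted p = 0.0216, and adjusted p = 0.638 with an estimated correlation), but not without WT replicate 1, TLR4ΔIEC replicate 1 or TLR4ΔIEC replicate 2 (adjusted p 0.131, 0.351 and 0.202, range 2.74e-06 to 0.402). MHC class II genes were lower as a list of 11 (median −0.73, camera adjusted p = 0.0146, and adjusted p = 0.640 with an estimated correlation), with no member past either adjustment, and lost the call under each other scaling. They lost it as well without WT replicate 3, TLR4ΔIEC replicate 1 or TLR4ΔIEC replicate 2 (adjusted p 0.112, 0.0654 and 0.822, range 3.03e-05 to 0.822). The invariant chain Cd74 had a value of −0.99 and H2-Ab1 of −0.86, and both were lowest in TLR4ΔIEC replicate 2.

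Cholesterol biosynthesis was the list with the most members higher adjusted over the list alone, 21 of 23, and none passed over all genes. All 23 genes had positive fold changes, as did all tested interferon and MHC class I genes. Fdps, the farnesyl diphosphate synthase, averaged 121.0 ± 7.94 TPM in WT and 219.9 ± 73.1 TPM in the libraries labelled TLR4ΔIEC. Sqle, the squalene epoxidase, and Hmgcs1, the HMG-CoA synthase, had log2 fold changes of 0.91 and 1.14. The list's median was 0.81 (camera adjusted p = 3.07e-10, and adjusted p = 0.567 with an estimated correlation). Under the other scalings 13 to 17 members were higher adjusted over the list alone.

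Tight junction, stress and catabolic lists were higher as well. Of 18 tight junction genes, 12 were higher adjusted over the list alone, a number that fell to between 1 and 6 under the other scalings. The claudins Cldn7, Cldn3 and Cldn2 had log2 fold changes of 0.62, 0.94 and 1.49, and the median was 0.61 (camera adjusted p = 4.85e-04, and adjusted p = 0.567 with an estimated correlation). Of 20 immediate early and heat shock genes, 10 were higher adjusted over the list alone, against 2 to 7 under the other scalings. Junb, Klf4 and Egr1, early response transcription factors, had values of 0.97, 0.49 and 2.20, and the median was 0.77 (camera adjusted p = 0.00105, and adjusted p = 0.567 with an estimated correlation). Of 21 glycolysis and hypoxia genes, 7 were higher adjusted over the list alone and 0 to 2 under the other scalings, and Ldha and Tpi1 had values of 0.47 and 0.23 (median 0.40, camera adjusted p = 0.00711, and adjusted p = 0.567 with an estimated correlation). Tpi1 turned negative under quantile normalization and with alpha-defensin, mitochondrial and 18S-like genes left out. Of 24 cell death and inflammasome genes, Casp8, Gsdmd, Naip1 and Nlrc4 were higher adjusted over the list alone, with 0 or 1 under the other scalings, and the adaptor Pycard and the cell cycle inhibitor Cdkn1a had values of 0.32 and 0.49 (median 0.44, camera adjusted p = 0.00759, and adjusted p = 0.567 with an estimated correlation). Of 18 autophagy genes, Atg9a, Atg12, Sqstm1 and Lamp2 were higher adjusted over the list alone and 0 under each other scaling, and Lamp1 and Gabarap had values of 0.47 and 0.58 (median 0.42, camera adjusted p = 0.00695, and adjusted p = 0.567 with an estimated correlation). Without TLR4ΔIEC replicate 2 the glycolysis and autophagy lists had adjusted p of 0.0615 and 0.0530 (ranges over alternatives 4.82e-05 to 0.0944 and 4.17e-05 to 0.0530). The cell death list had 0.0580 without WT replicate 1 and 0.0505 without TLR4ΔIEC replicate 1 (range 1.32e-04 to 0.0728). Pycard turned negative with alpha-defensin, mitochondrial and 18S-like genes left out.

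**Figure D3:**
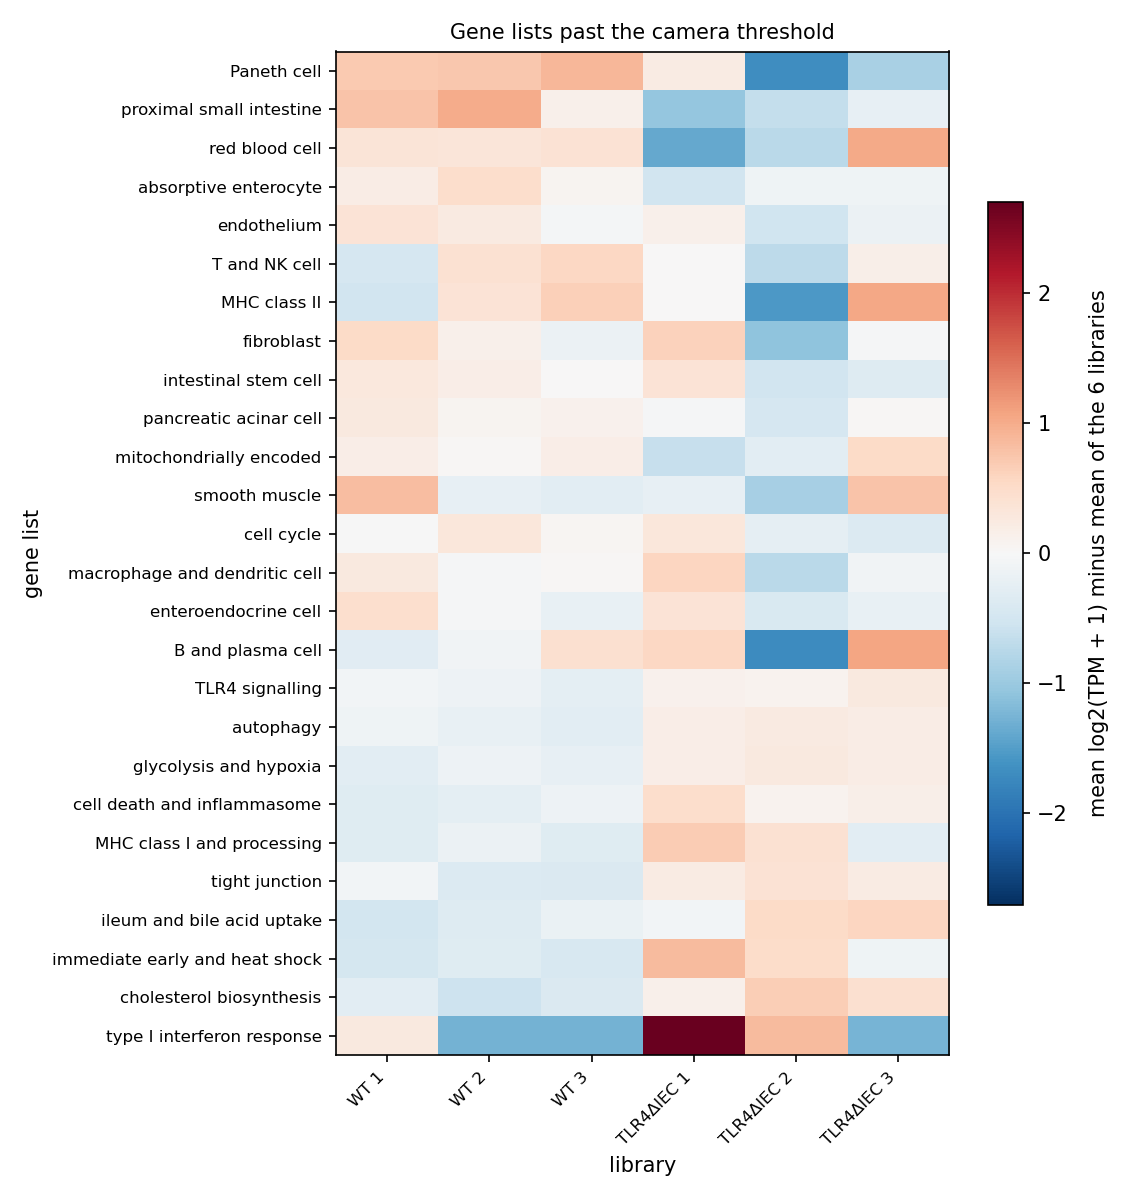
Mean log2(TPM + 1) of each of the 26 gene lists past the camera threshold (y axis) in each library (x axis), minus the mean of the 6 libraries; red is above and blue below that mean. Paneth cell genes run from −1.69 in TLR4ΔIEC replicate 2 to 0.90 in WT replicate 3, and type I interferon response genes from −1.28 in WT replicate 2 to 2.67 in TLR4ΔIEC replicate 1.

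Stromal lists were lower, with TLR4ΔIEC replicate 2 the lowest library in the endothelium, fibroblast and smooth muscle lists. The red blood cell, pancreatic acinar and mitochondrially encoded lists were lower as well. Endothelial genes had a median of −0.39 (13 genes, camera adjusted p = 5.88e-06), with values of −0.63 for Plvap and 0.17 for Egfl7, which turned negative under median-of-ratios scaling and with alpha-defensin, mitochondrial and 18S-like genes left out. Fibroblast genes had a median of −0.36 (15 genes, camera adjusted p = 0.00162), with values of 0.17 for Gsn, negative under each other scaling, and −0.83 for Dcn, which turned to 0.04 without TLR4ΔIEC replicate 2. Gsn was also negative without TLR4ΔIEC replicate 1 (−0.02) and Egfl7 without TLR4ΔIEC replicate 3 (−0.04). Smooth muscle genes had a median of −0.23 (14 genes, camera adjusted p = 0.0102), with values of −0.24 for Myl9 and −0.22 for Acta2, both of which turned positive without WT replicate 1 (0.14 and 0.18) and without TLR4ΔIEC replicate 2 (0.22 and 0.18). With an estimated correlation these 3 lists had an adjusted p of 0.583, 0.628 and 0.643, and no member passed either adjustment. Under median-of-ratios scaling, quantile normalization and with alpha-defensin, mitochondrial and 18S-like genes left out, 2 endothelial members were lower adjusted over the list alone. Under quantile normalization 1 fibroblast member was. The fibroblast call was lost without TLR4ΔIEC replicate 2 (adjusted p = 0.165, range 1.61e-05 to 0.165). The smooth muscle call was lost without WT replicate 1, TLR4ΔIEC replicate 1 or TLR4ΔIEC replicate 2 (adjusted p 0.457, 0.103 and 0.165, range 7.76e-06 to 0.565), under median-of-ratios scaling and with alpha-defensin, mitochondrial and 18S-like genes left out. Red blood cell genes had a median of −0.71 (4 genes, camera adjusted p = 0.0173, and adjusted p = 0.583 with an estimated correlation), with values of −0.90 for Hba-a2 and −0.77 for Hbb-bs, and lost the call without TLR4ΔIEC replicate 1 (adjusted p = 0.327, range 4.37e-07 to 0.327) and under each other scaling but quantile normalization. Of 26 genes fixed as pancreatic acinar markers 7 were tested, and Cpa1, Prss1 and Prss2 read 0 TPM in each library, so the list does not track acinar cells. Of the 7, colipase Clps was lower adjusted over the list alone (−2.25), while Zg16, also a goblet cell gene, had a value of 0.93 (median −0.29, camera adjusted p = 0.0441, and adjusted p = 0.567 with an estimated correlation), and the call was lost under each other scaling. It was also lost without WT replicate 1 or 3 and without TLR4ΔIEC replicate 1 or 3 (adjusted p 0.403, 0.0540, 0.0857 and 0.0867, range 0.0217 to 0.403). Mitochondrially encoded genes had a median of −0.43 (15 genes, camera adjusted p = 0.00382, and adjusted p = 0.628 with an estimated correlation), with values of −0.43 for mt-Atp8 and 0.17 for mt-Co1, which turned negative under median-of-ratios scaling. That call was lost under quantile normalization and without TLR4ΔIEC replicate 1 (adjusted p = 0.326, range 4.37e-07 to 0.326).

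The other lists did not pass. Enteric neuron and glia genes had a median of −0.32 (camera adjusted p = 0.0617) and passed without WT replicate 2 or TLR4ΔIEC replicate 3 (0.0172 and 0.00144, range 0.00144 to 0.514). Adipocyte genes had a median of 0.24 (camera adjusted p = 0.386) and passed as lower without WT replicate 3 (0.0225, range 0.0225 to 0.896). Among PPAR targets and fatty acid oxidation genes, the dehydrogenase Acadl was higher adjusted over the list alone (1.22), with 0 higher under each other scaling and 1 lower under median-of-ratios scaling and quantile normalization. That list had a median of 0.36 (camera adjusted p = 0.194) and passed without WT replicate 1 (0.0322, range 0.0322 to 0.907). Of the xenobiotic metabolism genes Cyp2b10 was lower adjusted over the list alone, and the list had a median of 0.09 and a mean of −0.01 (camera adjusted p = 0.137). It passed as lower without WT replicate 2 or TLR4ΔIEC replicate 2 (0.0253 and 0.00177, range 0.00177 to 0.933). The unfolded protein response had a median of 0.13 (camera adjusted p = 0.901) and passed as lower under quantile normalization. Ribosomal protein genes had a median of 0.16 (camera adjusted p = 0.366) and passed without TLR4ΔIEC replicate 1 (0.0267, range 0.00586 to 0.876). Nuclear genes of oxidative phosphorylation had a median of 0.21 (camera adjusted p = 0.287) and passed without WT replicate 2 or TLR4ΔIEC replicate 1 (0.0413 and 0.00502, range 0.00502 to 0.979). Circadian clock genes had a median of 0.02 (camera adjusted p = 0.262) and passed as lower without TLR4ΔIEC replicate 2 (0.0218, range 0.0218 to 0.918). The medians of the unfolded protein response, ribosomal, xenobiotic and circadian lists were negative under each other scaling, that of oxidative phosphorylation under quantile normalization (−0.03) and with alpha-defensin, mitochondrial and 18S-like genes left out (−0.11), and that of adipocyte genes under the latter. The adipocyte, xenobiotic, unfolded protein response and circadian tests pointed lower than all genes despite their positive medians.

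Terms from the annotation columns of the table were tested in the same way. Of 311 KEGG pathways, 53 passed, 18 higher and 35 lower, and of 1672 GO biological processes 38 passed, 9 higher and 29 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.995. The leading lower pathways were immune ones, such as the intestinal immune network for IgA production (139 genes, median −1.24, camera adjusted p = 5.01e-32), of which 96 tested members were immunoglobulin genes. The antimicrobial term of innate immune response in mucosa (38 genes) had a median of −1.56. Higher terms included steroid biosynthesis (16 genes, median 0.72, camera adjusted p = 0.00497), lysosome (121 genes, median 0.34) and macroautophagy (28 genes, median 0.42).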

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

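The alternative that left out alpha-defensin, mitochondrial and 18S-like genes was chosen after seeing the data, and the others before. Over all alternatives, 1986 comparisons of a gene, picked by the rule or after its values were seen, with its alternative kept direction and side of the threshold, 65 lost the call, 55 gained one and 39 changed direction. For gene lists these numbers were 627, 82, 31 and 30. The kept comparisons include genes and lists that passed in neither fit, and only those past the threshold could lose a call. Edn2 kept its call in 6 of 18 alternatives, Gata4 in 7 of 18, Apoa4 in 10 of 18 and Grm4 in 10 of 17. S100g and Ugt2a3 kept it in 12 of 18, and Lct, Dnase1 and Enpp7 in 13 of 18. The value of a list is its mean log2 fold change minus the mean of all genes, and that of a gene its log2 fold change. Where nothing else is said, the cause was not tested.

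A pseudocount of 0.1 TPM left 6 lower genes, and the direction changed for Fgf15 at 0.0846. Without a filter 26866 genes were tested, and limma called 0 genes, 0 higher and 0 lower, with 3377 at an unadjusted p under 0.05. The direction changed for the tuft cell list at 0.11, the unfolded protein response list at 0.0498 and the Notch list at 0.000994. A mean of at least 5 TPM left 7 genes, 2 higher and 5 lower, and changed the direction of the ribosomal protein list at −0.0132. Tlr4 had no value there, since it fell below the filter. eBayes without trend left 6 lower genes.

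Median-of-ratios scaling left 3 higher genes and changed the direction of Pcna at −0.15, Gsn at −0.0294, Egfl7 at −0.0122, mt-Co1 at −0.0242, the list of other Toll-like receptors at 0.0781 and the ribosomal protein list at 0.0202. Quantile normalization left 60 terms and changed the direction of Pcna at −0.26, Tollip at −0.0343, Nfkb1 at −0.00986, Gsn at −0.12, Tpi1 at −0.00623, the tuft cell list at 0.0823, the list of other Toll-like receptors at 0.18, the ribosomal protein list at −0.046, the oxidative phosphorylation list at −0.0557 and the Notch list at 0.0378. Leaving out the 20 highest genes left 3 higher genes and changed the direction of Pcna at −0.13, Gsn at −0.00507 and the ribosomal protein list at 0.0308. Leaving out alpha-defensin, mitochondrial and 18S-like genes left 3 higher genes and 56 terms and changed the direction of Pcna at −0.27, Tollip at −0.0459, Nfkb1 at −0.0546, Gsn at −0.16, Egfl7 at −0.13, Tpi1 at −0.0974, Pycard at −0.00311, the tuft cell list at 0.0551, the NF-kB target list at −0.0319, the ribosomal protein list at 0.00639 and the oxidative phosphorylation list at 0.0436. The direction of a list is that of its test, which can differ from the sign of the mean near 0.

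Array weights called 136 genes, 98 higher and 38 lower, and 17 lists, and changed the direction of Pcna at −0.0138, Lyz2 at 0.0623, Myl9 at 0.30, Acta2 at 0.22, the tuft cell list at 0.22 and the oxidative phosphorylation list at −0.0101. With the replicate number as a block, 1 gene was called, 0 higher and 1 lower, 0 of them shared with the genes above, and the direction changed for the Notch list at 0.00963. With an estimated inter-gene correlation camera called 0 lists and 0 terms, and the correlations estimated within the lists were mostly above the preset one.

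Leaving out each library in turn gave 0 to 367 genes, 0 to 262 higher and 0 to 105 lower, with 18 to 29 lists and 74 to 114 terms. Without WT replicate 1 there were 32 genes, 9 of them among the 16, and without TLR4ΔIEC replicate 1 there were 367, with all 16 among them. Without WT replicate 3 and TLR4ΔIEC replicate 3 there were 3 and 5, and without WT replicate 2 and TLR4ΔIEC replicate 2 there were 0, with 1681 and 2651 genes at an unadjusted p under 0.05. Fewer libraries give the test fewer degrees of freedom. Tlr4 stayed positive, at 0.88 to 1.15, in the 5 omissions that gave a value. Among genes that changed direction, the range over the omissions went for Pcna from −0.10 to 0.14, Myl9 from −0.76 to 0.22, Acta2 from −0.57 to 0.18, Fgf15 from −1.44 to 1.08, Gsn from −0.0196 to 0.35, Cd79a from −0.49 to 1.71, Lyz2 from −0.88 to 0.41, Dcn from −1.51 to 0.0443, Egfl7 from −0.0406 to 0.37 and Ighm from −0.0604 to 2.32. Among lists it went for the adipocyte list from −0.39 to 0.30, the Notch list from −0.0938 to 0.0878, the unfolded protein response list from −0.0997 to 0.0702, the tuft cell list from −0.34 to 0.24, the xenobiotic metabolism list from −0.37 to 0.24, the list of other Toll-like receptors from −0.12 to 0.11, the B and plasma cell list from −0.71 to 0.60, the ribosomal protein list from −0.0356 to 0.16 and the oxidative phosphorylation list from −0.0876 to 0.25. Read depth cannot be had from TPM, so what it limits is unknown.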

Other observations

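The tests of scaling for the regional markers, of shared defensin reads, of fewer crypts, of immune or stromal cells and of exchanged labels were chosen after the result they measure was seen. The first replaced one written before, the ileal median minus that of all genes, which a factor common to all genes of a library cannot change. Immunoglobulin genes took 3.18, 2.42 and 2.51% of the TPM in WT and 1.04, 0.250 and 1.03% in the libraries labelled TLR4ΔIEC. Of 189 tested, 179 had negative log2 fold changes, with a median of −1.82, and 3 passed the threshold. Segments share near-identical sequence, so single ones are uncertain.

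Clock genes, chosen after their values were seen, went in both directions: 5 were higher and 1 lower adjusted over the list alone. Under the other scalings these numbers were 4 and 4 (median-of-ratios), 4 and 3 (quantile), 5 and 2 (20 highest genes left out) and 4 and 5 (alpha-defensin, mitochondrial and 18S-like genes left out). Among the higher, Arntl, Npas2, Cry1 and Nfil3 had log2 fold changes of 1.64, 1.27, 0.89 and 1.67, and the lower one was Dbp at −2.09. Nr1d1 had −1.28 and did not pass. None passed over all genes tested. The hour of collection is not given.

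Markers of the proximal gut were lower and those of the ileum higher in the libraries labelled TLR4ΔIEC. A factor common to all genes of a library was argued against, since it moves both lists alike, and the ileal minus proximal score differed by 1.94, beyond the SD within WT (0.561) and within the libraries labelled TLR4ΔIEC (0.190), with no overlap. That difference restates the changes of both lists given above, so it is no separate evidence for the regional pattern. A more distal stretch of gut in the libraries labelled TLR4ΔIEC stays open: 11 Hox genes, ordered along the gut and in no list, had a median 0.22 above that of all genes, at the 99.6th percentile of 10000 random lists. Of these 11 genes, 8 had positive and 3 negative log2 fold changes. The percentile overstates the evidence, since the random lists were drawn gene by gene. Hoxb6, Hoxb7, Hoxb8 and Hoxb9 are neighbours that varied together, each highest within WT in replicate 1. Against a more distal stretch as the whole cause, S100g and Slc40a1, proximal genes, had log2 fold changes of 3.00 and 1.51, and WT replicate 1 had Hoxb9 at 8.74 TPM, against 0.70 and 0.53 TPM in the other WT libraries, with the lowest Fabp6, 2352 TPM. The genotype also stays open, untested, and the stretch and the genotype were not separated by the design.

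Paneth genes were lower in the libraries labelled TLR4ΔIEC. Scaling was argued against by a median of −1.79 under median-of-ratios scaling, and shared defensin reads by a median of −1.58 over the 9 Paneth genes that are not alpha-defensins, all 9 lower. The Paneth minus stem score differed by −1.23, beyond the SD within WT (0.244) and within the libraries labelled TLR4ΔIEC (0.518). It restates the changes of both lists given above and is no separate evidence. Stem genes did not move as one, however. The crypt marker Olfm4 had a log2 fold change of −1.53, near the Paneth median of −1.59, and Axin2 of 0.61. Fewer crypts as the whole cause were therefore argued against only as far as the stem list as a whole stands for crypts. Position along the gut and the genotype stay open.

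Tlr4 was higher, not lower, in the libraries labelled TLR4ΔIEC. The 56 macrophage, fibroblast, endothelium and smooth muscle genes had a median of −0.33 (SD 0.303 across genes, not mice). That argued against a rise of immune or stromal cells as large as that of Tlr4 on average over the group. TLR4ΔIEC replicate 2 weighed on that average, with macrophage, fibroblast and smooth muscle scores of −0.74, −1.08 and −0.89. TLR4ΔIEC replicate 1 had the highest macrophage and fibroblast scores of the 6 libraries, 0.57 and 0.62, with endothelium at 0.13 and smooth muscle at −0.22. The group median also does not cover TLR4ΔIEC replicate 3, where Tlr4 was highest at 4.81 TPM. There the smooth muscle, MHC class II and B and plasma cell lists stood 0.78, 1.04 and 1.07 above the mean of the 6 libraries. The macrophage, fibroblast and endothelium lists stood at −0.09, −0.04 and −0.16. More such cells in TLR4ΔIEC replicates 1 and 3 stay open. Over the scalings the Tlr4 log2 fold change ran from 0.80 to 1.01, above the 0.5 set beforehand for arguing against scaling. Scaling is left open all the same, since Tlr4 averaged 0.640 TPM in WT, near the floor. The 0.80 also lay above 0.5 by less than the standard error of 0.40, a margin that was not part of that rule and measures spread between mice. Exchanged group labels cannot be told apart from the genotype with an adjusted p of 0.243, since transcript left by the deletion was not measured. Genes within 10 Mb of Tlr4 had an unadjusted p under 0.05 in 14 of 47 cases, against 2833 of 13411 elsewhere (Fisher's exact test, two-sided, odds ratio 1.58, 95% interval 0.782 to 3.05, p = 0.153), which leaves open flanking sequence of another strain.

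The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split gave 16 genes, and the highest other split 3 (1 split as large, the real one). It gave 6 higher genes against 2 (1 split) and 10 lower against 2 (1 split). For lists the real value and the highest other were both 26 (2 splits), and for terms 91 and 130 (5 splits).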
